A study of Mus musculus with 6 samples.

How the data were processed

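Cells of the knee synovium, the tissue that lines the joint, were profiled by droplet-based single-cell RNA sequencing with a 3' kit from 10x Genomics. In this method each captured transcript carries a unique molecular identifier (UMI), so that amplified copies of a molecule are counted once. Per the labels, tissue of 10 mice was pooled for each library, living cells were sorted without a gate for cell type, and 7000 cells were loaded. The 6 libraries form 6 groups of 1 library: healthy wild type, healthy Notch3 knockout, arthritic wild type, arthritic Notch3 knockout, arthritic mice given an isotype control antibody, and arthritic mice given an antibody against Notch3. Arthritis was brought on by K/BxN serum transfer, in which serum of autoimmune K/BxN mice inflames the joints of the recipients.

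The deposited matrices hold raw UMI counts per gene and cell barcode. Cell Ranger 3.0.2 and the mouse genome build mm10 are named in the submitters' processing notes. Each of the 18491 deposited barcodes held more than 500 genes and less than 20% mitochondrial UMIs, so a filter had been applied before deposit; its description is not given in the sources used here. The library tags in the barcodes are numbered close together within each arthritic pair and far apart in the healthy pair, so a batch difference between the healthy libraries cannot be told apart from their genotypes. Notch3 was placed with the GENCODE annotation of the same build.

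Barcodes with fewer than 200 genes (none) or more than 10% mitochondrial UMIs (414) were left out. Scrublet, run per library through scanpy 1.11.5 with an expected rate of 0.03, marked 161 doublets (0.89% of 18077). It marked 3 in the isotype library and 103 in the healthy knockout library. The 18077 barcodes, doublets included, were scaled, log-transformed and clustered together on 2000 variable genes. This used 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. The doublets were then left out, and 17916 cells remained. Genes of the Notch lists, dissociation stress, sex-linked, haemoglobin, mitochondrial, ribosomal and predicted genes were kept out of the genes for clustering. Markers of 20 cell classes were fixed before the data were examined, as were the lists, tests and alternatives below except where stated. The rule that scored clusters with these markers was chosen after seeing the data, as was the pooling of tendon-led clusters (11 and 12) with fibroblasts and of dendritic-led clusters (17 and 22) with myeloid cells. Of 25 clusters, 1 cluster of 175 cells (doublets included) led by proliferation genes stayed unnamed.

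Raw counts were summed per library and class. Levels are CPM (counts per 10000 counts, times 100): the UMIs of a gene scaled by all UMIs of the class in that library, with exact Poisson intervals, and shares of cells have exact Clopper-Pearson intervals, both at 95%. A count of 0 was bounded by its interval, and a fold against a group at 0 was taken against a floor of 3 counts over the group. These intervals cover counting error only, not the spread between mice or libraries. With 1 library per group, a ratio within a pair has no replicate check and no test. For 28 gene lists fixed beforehand, the median log2 ratio (pseudocount of 0.5 UMIs, members with at least 20 UMIs) was set against 10000 random lists of the same size matched on expression, and a member counted as higher or lower at 1.5-fold.

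The libraries form 3 pairs that differ in whether Notch3 was targeted: healthy genotype, arthritic genotype and arthritic antibody. The planned test was edgeR 4.0.16's quasi-likelihood test (TMM scaling, filterByExpr) with terms for pair and for Notch3 targeting, on classes with at least 30 cells in each library, with Benjamini-Hochberg adjustment and a threshold of 0.05. It leaves 2 residual degrees of freedom and treats knockout and antibody as repeats of a shared Notch3 effect. The arthritis effect is the contrast of the arthritic with the healthy genotype pair in that fit. After the data had been seen, a model with separate Notch3 effects in the healthy pair and in the 2 arthritic pairs was added (1 residual degree of freedom). It gives the Notch3 effect in the 2 arthritic pairs and the difference between arthritic and healthy pairs, and it assumes that the lone healthy pair varies like the arthritic pairs. A contrast of the wild-type libraries from this model was also run and is not reported, because it compares single libraries. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. No group has a replicate library. The spread behind the edgeR p-values is the disagreement of the Notch3 effect between pairs: among all 3 in the planned fit, and between knockout and antibody in the added model. The camera p-values compare a list with the other genes at the given correlation.

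Genes were named by a rule: Notch3 in each library; per effect and class, up to 5 genes with the largest rise and fall among those passing the test, with a mean of at least 20 CPM in the higher group and the same direction in each pair; where fewer than 3 passed, the 5 with the smallest p. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked, predicted and dissociation stress genes were left out of this ranking. Members of the Notch lists could also be named, and of each other list the 4 members with the largest ratio in a pair or the smallest p in a tested effect.

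Alternatives were DESeq2 1.42.0, median-of-ratios or library-total scaling, no filter on low counts, cells with at least 500 genes and at most 5% mitochondrial UMIs, doublets kept, each pair left out, other Leiden resolutions (0.5 and 2), a stromal denominator, at least 50 UMIs per list member, cells thinned to 1000 UMIs, and an estimated correlation for camera. The fits were tested on simulated counts drawn with the dispersion and gene numbers of the planned fit, also for the added model, whose own common coefficient of variation was lower (0.174, 0.168 and 0.228 against 0.255, 0.279 and 0.268 in fibroblasts, endothelial and myeloid cells). For the planned model they recovered 95.9% of 4-fold and 28.9% of 2-fold changes among 12852 fibroblast genes, 76.3% and 13.8% among 6885 endothelial genes, and 93.7% and 21.9% among 10362 myeloid genes. For the added model they recovered 76.8% of 4-fold and 8.2% of 2-fold changes in fibroblasts, 45.5% and 2% in endothelial cells, and 66.0% and 4.1% in myeloid cells. Mural cells numbered 9 to 33 per library, so their planned test and its alternatives were not run. Python 3.11.15 and R 4.3.3 were used.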

Results

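Single-cell transcriptomes of mouse knee synovium were compared to ask how Notch3 shapes synovial fibroblasts in healthy and arthritic joints. Each of the 6 groups had 1 library. Before filtering, the libraries held 2977 (healthy wild type), 5096 (healthy knockout), 2452 (arthritic wild type), 2666 (arthritic knockout), 3191 (isotype) and 2109 (anti-Notch3) barcodes. Their total UMI counts were 23627904, 24535233, 12017317, 11889232, 21065113 and 11636998, and the median UMI counts per barcode were 7561, 4533.5, 3988, 4310, 6130 and 5072. After filtering, 2903, 4897, 2385, 2651, 3037 and 2043 cells remained, in the same order.

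Notch3, a receptor of the Notch family that is most abundant in mural cells of vessels, lies on chromosome 17 (mm10, 32120820 to 32166852, minus strand, protein coding). Over all cells it was at 4.96 CPM (interval 4.09 to 5.96) in healthy wild type and 0.299 (0.12 to 0.616) in healthy knockout cells. In arthritis it was at 5.58 (4.32 to 7.1) in arthritic wild type and 0.254 (0.0523 to 0.741) in arthritic knockout cells. The isotype library had 3.30 CPM (2.56 to 4.19) and the anti-Notch3 library 2.21 (1.43 to 3.26); an antibody against the receptor need not lower its transcript. In the mural class, Notch3 was at 549 CPM (352 to 817), 421 (282 to 605) and 351 (240 to 495) in the healthy wild-type, arthritic wild-type and isotype libraries. It was at 0 (upper bound 61.4) in the healthy knockout library and at 28.0 (3.39 to 101) in the arthritic knockout library. Which part of the gene the knockout removes is not given in the sources used here, so it is unknown whether the 3' tag lies inside it.

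Fibroblasts and myeloid cells made up most of each library. Fibroblasts were 43.6% of arthritic wild-type cells (interval 41.6 to 45.6) and 65.0% of arthritic knockout cells (63.2 to 66.8), and myeloid cells were 42.6% (40.6 to 44.6) and 17.8% (16.3 to 19.3). The antibody pair differed the other way, with 68.4% fibroblasts (66.7 to 70.1) under isotype and 52.7% (50.5 to 54.9) under anti-Notch3, and 19.7% (18.3 to 21.2) and 38.2% (36.1 to 40.3) myeloid cells. Healthy wild-type and knockout libraries held 61.3% (59.5 to 63.1) and 74.6% (73.4 to 75.8) fibroblasts and 26.2% (24.7 to 27.9) and 17.8% (16.7 to 18.9) myeloid cells. Endothelial cells ranged from 4.45% in the healthy knockout to 9.05% in the arthritic knockout library. Neutrophils were 3.69% (2.97 to 4.53) of arthritic wild-type cells, 1.09% (0.734 to 1.57) of arthritic knockout cells and 0.362% (0.181 to 0.647) of isotype cells; 0 of 2043 anti-Notch3 cells were neutrophils (upper bound 0.180%). Shares had no replicate check, and with finer clustering the fibroblast shares of the healthy libraries were 57.9% and 58.5%. There a cluster of 1127 cells led by Clic5, Tspan15 and Hbegf stayed unnamed, although these genes lead a fibroblast cluster in the main clustering. The shares of the clusterings thus do not cover the same cells.

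**Figure D1:**
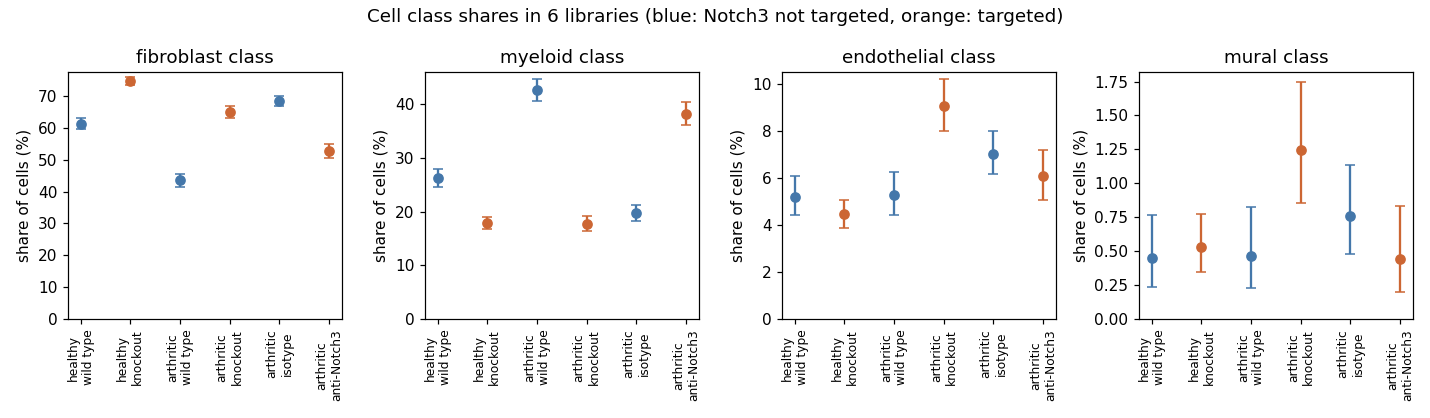
Share of cells (%, vertical axis) in 4 classes for each of the 6 libraries (horizontal axis), blue where Notch3 was not targeted and orange where it was; bars are exact 95% Clopper-Pearson intervals. The fibroblast share is 43.6% in arthritic wild type and 65.0% in arthritic knockout cells but 68.4% under isotype and 52.7% under anti-Notch3.

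The central comparison asked what targeting Notch3, by knockout or antibody, did to fibroblasts in arthritic joints. Mmp3, Saa3, Cxcl5 and Tnfsf11 were far lower with Notch3 targeted in both arthritic pairs, while other members of their gene groups were not, such as the neutrophil-attracting chemokine Cxcl1 (log2 ratios of 1.72 and 1.32). Mmp3, which encodes the matrix-degrading enzyme stromelysin, was at 1222 CPM (1200 to 1250) in arthritic wild type and 65.4 (60.0 to 71.2) in arthritic knockout fibroblasts, and at 894 (880 to 909) under isotype and 73.1 (66.9 to 79.7) under anti-Notch3. Saa3, an acute-phase serum amyloid gene, was at 1494, 7.24, 664 and 8.49 CPM in the same order, and Cxcl5, a neutrophil-attracting chemokine, at 235, 0.246, 89.0 and 2.30 CPM. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, was at 30.4, 0.614, 28.0 and 1.58 CPM. Higher with Notch3 targeted were the chemokine Ccl11 (50.1 and 363 CPM in the genotype pair, 15.8 and 93.2 in the antibody pair) and Cd34, a surface marker of sublining fibroblasts (223 and 618, 209 and 518 CPM).

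In the added model, 400 of 13447 fibroblast genes changed in the 2 arthritic pairs by edgeR: 243 rose and 157 fell (2407 at an unadjusted p under 0.05, 380 by DESeq2). The genes with the largest rises on the log2 scale were Scg3 (3.16, SE 0.215, adjusted p = 0.00688), Myoc (2.95, SE 0.201, adjusted p = 0.00688) and Ccl11 (2.77, SE 0.181, adjusted p = 0.00651). They were followed by the B-cell-attracting chemokine Cxcl13 (2.60, SE 0.429, adjusted p = 0.0368) and Amy1 (2.55, SE 0.194, adjusted p = 0.00778). Saa3 fell by 6.93 (SE 0.409, adjusted p = 0.00577), Cxcl5 fell by 6.86 (SE 0.723, adjusted p = 0.0134), and the haptoglobin gene Hp fell by 5.69 (SE 0.676, adjusted p = 0.0184). Olfr810 fell by 8.37 (SE 0.523, adjusted p = 0.00577) from 29.1 and 23.3 CPM. Msmp fell by 8.17 (SE 0.382, adjusted p = 0.00352), but its UMIs came almost entirely from the arthritic wild-type library (116 CPM against 0.245 under isotype). Of the 400 genes, 43 were at least 5-fold higher in endothelial or myeloid cells. Mural, erythroid and other cells were not part of this comparison. Fitted on the 4 arthritic libraries alone, edgeR called 294 genes, 292 of them among the 400.

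In these arthritic fibroblasts, the matrix genes that changed fell, and the lining genes that changed rose except Tspan6. Among 18 collagen and matrix genes 0 rose and 7 fell (adjusted over the list alone, 0 higher and 12 lower), including the tenascin Tnc, which fell by 4.30, Col12a1, which fell by 2.66, and the metalloproteinase inhibitor Timp1, which fell by 1.82. Among 16 matrix-degrading and bone-resorption genes 0 rose and 5 fell (adjusted over the list alone, 0 and 6): Mmp3 fell by 3.86, Tnfsf11 fell by 4.70, Acp5 fell by 1.12 and Mmp19 fell by 1.09, besides Mmp2. Mmp13, a collagenase, had 0 UMIs in arthritic knockout fibroblasts (upper bound 0.453 CPM against 288 in wild type) but stayed at 124 CPM under anti-Notch3 against 289 under isotype. Of 13 genes of lining fibroblasts, which face the joint space, 5 rose and 1 fell (adjusted over the list alone, 9 and 2): Timp3 rose by 1.69, Hspb7 by 1.45 and Clic5 by 1.21, and Tspan6 fell by 1.16. Of 18 sublining genes, 2 rose and 0 fell (adjusted over the list alone, 7 and 1): Cd34 by 1.45 and the lipocalin Apod by 1.18. The cytokine and chemokine list split, with 4 of 22 members rising (Ccl11, Cxcl13, Cxcl1 and Csf1, a macrophage growth factor) and 3 falling (Saa3, Cxcl5 and the interleukin 33 receptor Il1rl1); adjusted over the list alone these were 8 and 4. Dissociation stress genes, which mark handling of the tissue, moved with the targeted libraries too: 2 of 16 rose (Junb by 1.37 and Zfp36 by 1.22; adjusted over the list alone, 10 higher and 1 lower). Transcripts of other tissues differed alongside. Of 10 cartilage transcripts 0 passed, with a median of -2.34 (adjusted over the list alone, 1 higher and 7 lower; Col11a1 -3.31, Acan -3.73), and of 6 erythroid transcripts 3 rose (Hba-a1, Hba-a2 and Hbb-bs).

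**Figure D2:**
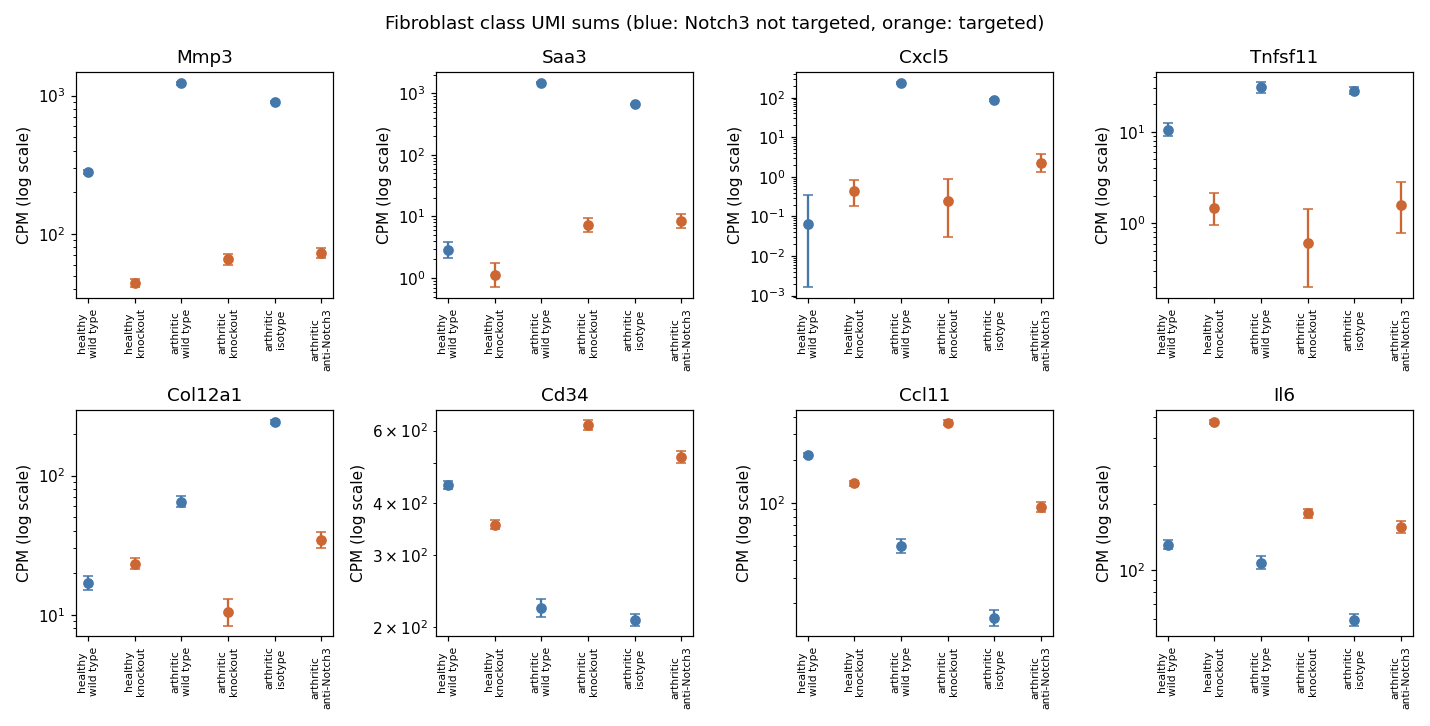
Levels of 8 genes in the fibroblast class (CPM, log scale, vertical axes) in the 6 libraries (horizontal axes), blue where Notch3 was not targeted and orange where it was; bars are exact 95% Poisson intervals. Mmp3 is at 1222 and 894 CPM in the arthritic libraries without targeting and at 65.4 and 73.1 CPM in those with it.

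Ratios of the 2 arthritic pairs were compared gene by gene to ask whether knockout and antibody moved the same genes. Across 8439 fibroblast genes with at least 100 UMIs in each pair, the log2 ratios had Pearson's r = 0.599 and Spearman's rho = 0.50, across genes, which are not independent replicates. Of 776 genes at least 1.5-fold apart in both pairs, 730 (94.1%) had the same direction. Collagen and matrix genes were lower by a median of -1.07 in the genotype pair and -1.08 in the antibody pair, with Col12a1 at -2.63 and -2.80 and the collagen cross-linking enzyme gene Lox at -3.25 and -1.59. The interferon response list was an exception: its median was -2.20 in the genotype pair, with 13 of 18 members lower (Oas1a -5.22, Rsad2 -3.92, Isg15 -3.35, Irf7 -3.31), and -0.06 in the antibody pair (Cxcl10 1.35, Ifit2 1.21). These genes also differed between the arthritic libraries without targeting, the isotype library lying below the wild type by a median of -1.07. The main clusters within the class differed too: cluster 7, led by Saa3, Hp, Slpi and Cxcl5, held 42.4% of arthritic wild-type and 28.9% of isotype fibroblasts but 0.06% of arthritic knockout and 2.04% of anti-Notch3 fibroblasts. Cluster 12, led by Fmod and Tnn, held 24.0% of isotype and 1.49% of anti-Notch3 fibroblasts, but 2.98% and 0.0% in the genotype pair. It thus also differed between isotype and arthritic wild type, neither of which was targeted. Cluster 0, led by Myoc and Apod, held 5.39% and 30.1% in the genotype pair and 1.30% and 12.5% in the antibody pair. Cluster 8, led by Mfap4 and Postn and at 0.28% and 0.25% in the healthy libraries, set knockout and antibody apart: it held 16.3% and 0.29% in the genotype pair but 24.0% and 19.0% in the antibody pair. Differences in the mix of cells and differences within cells were not separated.

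**Figure D3:**
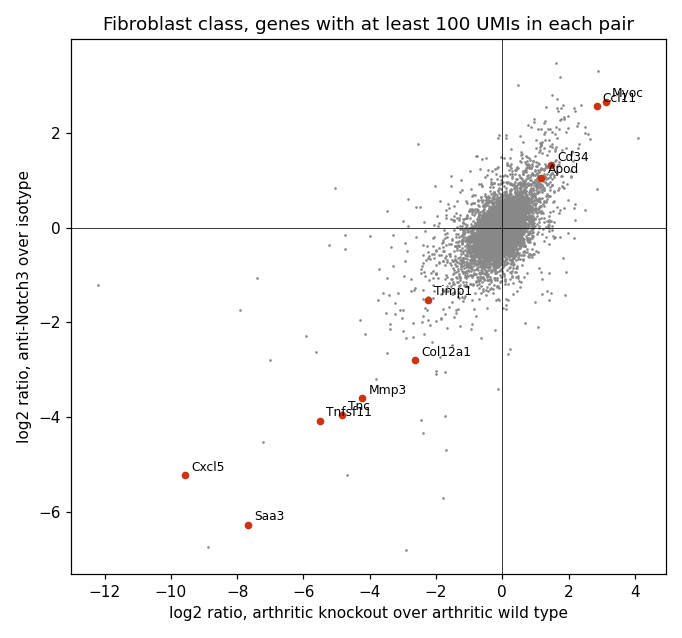
Log2 ratios of fibroblast genes with at least 100 UMIs in each pair, arthritic knockout over wild type (horizontal axis) against anti-Notch3 over isotype (vertical axis), each grey point a gene and named genes in red. Pearson's r across the 8439 genes is 0.599, and Saa3 and Cxcl5 lie far in the lower left.

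In healthy joints the comparison of knockout with wild type asked what the loss of Notch3 did without inflammation. Lining genes were higher in healthy knockout fibroblasts, by a median log2 ratio of 1.94 (9 of 13 members higher, 0 lower, percentile 100 of matched lists): Tspan15 by 2.26, Col22a1 by 2.21, Clic5 by 2.15 and Rab37 by 2.15. The mix of cells differed as well: cluster 1, led by Clic5, Hbegf, Prg4 and Tspan15, held 5.45% of healthy wild-type and 23.0% of healthy knockout fibroblasts, and cluster 6, led by Cfd and Sfrp4, 32.1% and 7.20%. Prg4, the gene of the joint lubricant lubricin and chosen after its values were seen, was at 23500 CPM in healthy knockout and 11150 in healthy wild-type fibroblasts. Matrix-degrading genes were lower by a median of -0.71 (10 of 15 members lower): Mmp13 by -3.26, Tnfsf11 by -2.83 and Mmp3 by -2.67, the last from 280 CPM (272 to 289) to 44.1 (41.1 to 47.2). The inflammatory cytokine Il6 was higher, at 472 CPM against 131 in wild type, and Cxcl13 lower, at 42.0 against 210 CPM. Across all classes of genes the directions in the 2 genotype pairs often differed: of 567 genes at least 1.5-fold apart in both genotype pairs, 293 (51.7%) had the same direction (r = 0.05 across 8474 genes, rho = -0.03). In the healthy pair, transcripts of other cell types differed in both directions among fibroblasts (Hbb-bs -6.47, S100a9 -3.04, Bglap 3.94, H2-Aa 2.54). Of the dissociation stress genes, Zfp36 (1.29), Ier2 (1.27), Atf3 (1.20) and Nr4a1 (1.13) were higher in the knockout and some others lower. Their bearing on the ratios above was not tested. The healthy pair has no replicate, and median-of-ratios scaling moves its fibroblast ratios by 0.114 on the log2 scale.

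Over all 3 pairs together, the planned test asked for a Notch3 effect shared by healthy and arthritic fibroblasts. Mmp3 was lower with targeting in 3 of 3 pairs, by -3.44 on the log2 scale (SE 0.345, adjusted p = 0.178). So were the cell adhesion gene Chl1, by -2.57 (SE 0.214, adjusted p = 0.0790), and Edil3, by -2.28 (SE 0.171, adjusted p = 0.0581). Olfr810 (-8.13, SE 0.559, adjusted p = 0.0572) was lower in the 2 arthritic pairs, with 1 UMI in healthy wild type and 0 in healthy knockout, and Ifi202b (-9.58, SE 0.494, adjusted p = 0.0572) in 2 of 3 pairs. No gene passed: edgeR called 0 of 12852 (1081 at an unadjusted p under 0.05), whereas DESeq2 called 172; edgeR called 294 without the healthy pair, 9 without the antibody pair and 0 without the arthritic genotype pair. Among lists in camera, lining genes lay above other genes (adjusted p = 7.53e-06, median 1.07; 8 members adjusted over the list alone), led by Clic5 (1.55), Tspan15 (1.57) and Itga6 (1.35). Collagen and matrix genes lay below (adjusted p = 7.87e-06; Lox -1.93, Col3a1 -0.89), as did matrix-degrading genes (adjusted p = 3.8e-05; Mmp3, Tnfsf11 -3.91), while dissociation stress genes lay above (adjusted p = 5.11e-06; Zfp36 1.27, Ier2 1.15). None of these calls held: adjusted p = 0.708, 0.708, 0.588 and 0.588 with an estimated correlation. That correlation was estimated with 2 residual degrees of freedom, and no list passed with it in any class, so the calls stay unsettled.

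**Figure D4:**
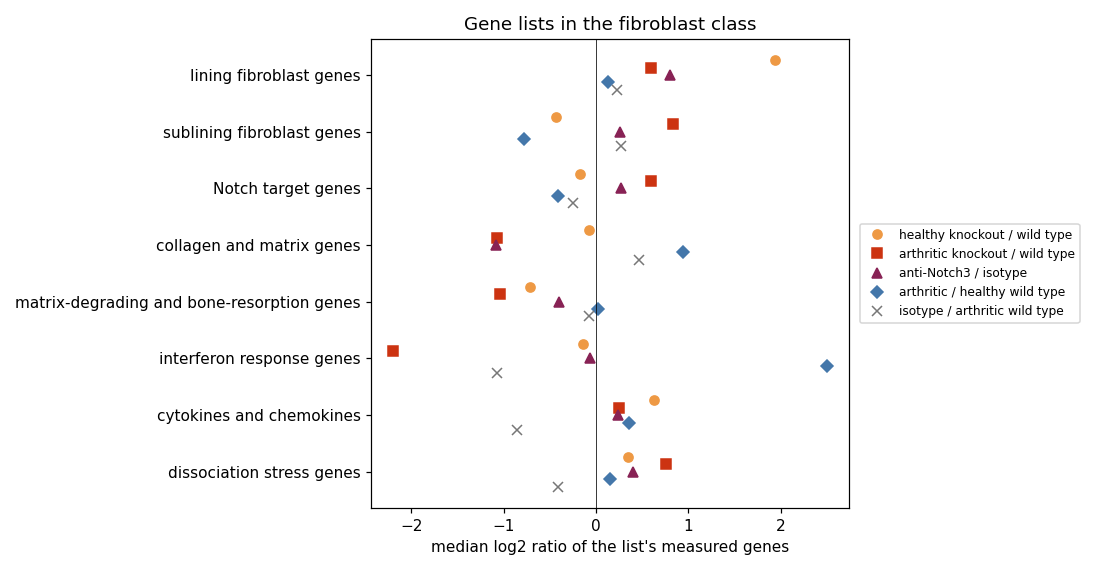
Median log2 ratio (horizontal axis) of the measured genes of 8 lists (vertical axis) in the fibroblast class, with a symbol for each of 5 comparisons of libraries. Lining genes sit at 1.94 in the healthy pair and at 0.59 and 0.81 in the arthritic pairs, and collagen and matrix genes at -0.07, -1.07 and -1.08.

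No gene of the Notch lists passed the test in arthritic fibroblasts. In fibroblasts, Notch3 itself had log2 ratios of -3.88 and -4.41 in the healthy and arthritic genotype pairs, each without a test. Hes1, a classical Notch target, was at 108, 97.2, 120, 141, 80.9 and 93.2 CPM in the healthy wild-type, healthy knockout, arthritic wild-type, arthritic knockout, isotype and anti-Notch3 libraries. Notch2 was at 31.2, 57.6, 43.0, 44.0, 39.0 and 26.6 CPM and the ligand gene Jag1 at 15.6, 13.9, 18.6, 12.8, 21.3 and 18.7 CPM. Heyl, another target, had 38, 43, 2, 18, 7 and 1 UMIs, so its level rests on few molecules. In the 2 arthritic pairs edgeR called 0 of 8 Notch targets and 0 of 5 receptors and ligands, with 0 adjusted over the list alone; the smallest adjusted p was 0.149, for Ptp4a3 (0.60 on the log2 scale, SE 0.173).

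Arthritis itself was compared by setting arthritic against healthy libraries of the same genotype. Each group is 1 library, and the tags of the healthy libraries lie far apart, so a batch difference could enter these comparisons. In wild-type fibroblasts Saa3 was at 2.86 CPM (2.09 to 3.83) when healthy and 1494 (1470 to 1520) when arthritic, Cxcl5 at 0.0636 (0.00161 to 0.354) and 235 (224 to 247). Mmp13 was at 11.6 (10.0 to 13.4) and 288 (275 to 300). Interferon response genes were higher by a median of 5.66-fold (12 of 18 members; log2 ratios of 5.09 for Oas1a, 4.58 for Rsad2 and 4.01 for Irf7). Collagen and matrix genes were higher by a median log2 ratio of 0.94 (11 of 18; Tnc 3.91, Postn 2.43, Timp1 2.37). Sublining genes were lower by -0.78 (11 of 18; Comp -2.21, Apod -1.38). In knockout fibroblasts the median log2 ratios of these lists were 0.17, -0.36 and 0.30, with Saa3 at 1.13 and 7.24 CPM. The planned contrast over both genotypes called 0 of 12852 genes by edgeR (543 at an unadjusted p under 0.05; 4 by DESeq2). The smallest p-values belonged to Olfr810 (8.37, SE 0.703, adjusted p = 0.329), higher in 1 of 2 genotypes, and Ccnb1ip1 (3.95, SE 0.408, adjusted p = 0.520), higher in 2 of 2. Hhip (-2.02), Cytl1 (2.16) and Il13ra2 (7.48) followed, each with adjusted p = 0.904. Cytl1 turned to -0.12 without the tendon-led clusters. In camera, interferon response and proliferation genes lay above others (adjusted p = 1.38e-05 for both; adjusted p = 0.716 with an estimated correlation), with Ifit3 at 1.92 and Rrm2 at 0.90.

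In endothelial cells, 7 arterial transcripts rose where Notch3 was targeted in arthritis, and 3 venous transcripts fell while the class held fewer cells of its venous cluster. Cluster 15, led by Selp, Lrg1, Emcn and Vwf, was 46.0% of arthritic wild-type and 22.9% of arthritic knockout endothelial cells, and 40.7% under isotype and 32.3% under anti-Notch3. Sox17, a transcription factor of arteries, was at 128 CPM (104 to 157) in arthritic wild type and 342 (295 to 395) in knockout cells, and at 149 (126 to 175) under isotype and 366 (307 to 432) under anti-Notch3. Cd74, the invariant chain of MHC class II, was at 42.3 (28.7 to 60.0), 185 (150 to 225), 8.02 (3.46 to 15.8) and 106 (75.7 to 144) CPM. Lrg1, a venous gene of inflamed vessels, was at 1511 (1420 to 1600), 594 (530 to 662), 1177 (1110 to 1250) and 618 (541 to 702) CPM. Glycam1, a ligand of L-selectin on high endothelial venules, was at 250 CPM in arthritic wild type and 61.2 under isotype, with 0 UMIs in the other 4 libraries.

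The added model called 1069 of 7743 endothelial genes in the 2 arthritic pairs by edgeR (640 rose, 429 fell; 1890 at an unadjusted p under 0.05), whereas DESeq2 called 160. With 1 residual degree of freedom, the model set a spread shared by all endothelial genes, and its p-values rest on that. The planned fit, with 2 residual degrees of freedom, did estimate spreads that differed between endothelial genes. P-values of the added model may therefore be too small for some genes. Of 12 arterial genes 7 rose and 0 fell (adjusted over the list alone, 8 and 0), among them Gkn3 by 4.35, Sox17 by 1.42, Fbln5 by 1.32 and the Notch target Hey1 by 1.63 (SE 0.373, adjusted p = 0.000257). Of 9 venous genes Vcam1 rose by 1.11, Lrg1 fell by 1.07, Ackr1 fell by 0.88 and Selp fell by 0.85. Of 9 antigen presentation genes 6 rose, including Cd74 by 2.72 (SE 0.283, adjusted p = 2.37e-19) and H2-Ab1 by 2.23. Cd74 stood at 0.234%, 0.737%, 0.0954% and 0.524% of its myeloid level in the arthritic libraries, and 9 myeloid markers at a median of 0.335%, 0.692%, 0.503% and 0.266% of theirs; myeloid RNA in the class was not separated from endothelial Cd74 and H2-Ab1. Of 6 macrophage inflammatory genes 5 fell in the class, Spp1 and Thbs1 among them. Of 9 Notch targets 4 rose (adjusted over the list alone, 6): Hey1, Ptp4a3 by 0.87, Nrarp by 0.89 and Lfng by 0.97. The largest rises were Tnfsf9 (5.17), Npr3 (4.73), Tmem182 (4.55), Lnx1 (4.47) and Slc28a2 (4.44). Their means in the arthritic libraries without targeting were only 0.501 to 1.504 CPM. There 3 UMIs would be 4.09 CPM (wild type) and 3.01 CPM (isotype), so the sizes of these rises rest on few molecules. The largest falls were Glycam1 (at least 43.2-fold lower, adjusted p = 5.69e-32), Mmp13 (at least 18.6-fold), Ms4a6d (at least 11.8-fold), Serpina3g (at least 8.31-fold) and Akr1b8, which fell by 5.24. Dissociation stress genes rose in 11 of 16 cases (Egr1 by 1.85), while Hspa1b fell. Markers of other cell types rose in the class too. Of 10 mural genes 4 rose (Acta2, Tagln, Des and Myl9) and Mcam fell, and of 15 sublining fibroblast genes 6 rose (Ly6c1, Mfap5, Gpx3, Cxcl12, Mgp and Comp) and 2 fell (Pi16 and Col15a1). Acta2 was at 13.6, 29.6, 35.1 and 300 CPM in the arthritic libraries. Of the 1069 genes, 60 were at least 5-fold higher in fibroblasts or myeloid cells. Mural and erythroid cells were not part of this comparison, so transcripts from them are not counted in it.

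Across 1847 endothelial genes, the ratios of the arthritic pairs had r = 0.742 and rho = 0.691, and 331 of 341 genes (97.1%) at least 1.5-fold apart in both had the same direction. Against the healthy pair the shares were 58 of 157 (36.9%, r = -0.156) for the arthritic genotype pair and 40 of 128 (31.2%, r = -0.214) for the antibody pair. The planned test over 3 pairs called 0 of 6885 genes by edgeR (560 at an unadjusted p under 0.05; 29 by DESeq2; 933 by edgeR without the healthy pair). Gkn3, an arterial gene, was higher with targeting in 3 of 3 pairs (4.91, SE 0.542, adjusted p = 0.0715), and Glycam1 lower in 2 of 3 pairs by at least 50.9-fold (adjusted p = 0.0715). Mmp14 (-2.88), Akr1b8 (-5.16) and Moxd1 (-4.22) were lower, with adjusted p = 0.137, 0.137 and 0.183. Arterial genes lay above other genes in camera (adjusted p = 2.37e-07; adjusted p = 0.527 with an estimated correlation; 4 members adjusted over the list alone), led by Gkn3. Arthritis gave 0 calls by edgeR (276 at an unadjusted p under 0.05; 1 by DESeq2). The smallest adjusted p was 0.320, for Glycam1 (at least 50.3-fold higher), followed by S100a8 (4.56, adjusted p = 0.347), Moxd1 (5.54, adjusted p = 0.426), and Acta2 (-3.30) and Akr1b8 (5.32) with adjusted p = 0.516. Red-cell transcripts differed between the healthy libraries: Hbb-bs was at 7774 CPM in healthy wild-type and 3.95 in healthy knockout endothelial cells.

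Among myeloid cells, the monocyte markers Ly6c2 and Plac8 and the cluster they lead were lower in the targeted library of each arthritic pair. Cluster 14 held 32.0% of arthritic wild-type and 6.37% of arthritic knockout myeloid cells, and 10.7% under isotype and 1.41% under anti-Notch3. Ly6c2, a marker of inflammatory monocytes, was at 874 CPM (842 to 908) in arthritic wild type and 150 (134 to 166) in knockout cells, and at 94.4 (82.4 to 108) under isotype and 20.9 (16.5 to 26.1) under anti-Notch3. Healthy wild type had 23.5 (19.7 to 27.9) and healthy knockout 2.68 (1.28 to 4.92). The arthritic libraries without targeting differed too, Ly6c2 being at 874 CPM in wild type and 94.4 under isotype. The isotype level thus lay below the 150 CPM of arthritic knockout cells. Cluster 14 likewise held 32.0% and 10.7% in these untargeted libraries. Arg1, an arginine-degrading enzyme, was at 63.8 (55.2 to 73.4), 0 (upper bound 1.63), 48.7 (40.2 to 58.4) and 1.34 (0.435 to 3.12) CPM in the arthritic libraries. Genes of tissue-resident macrophages were higher with targeting, by a median log2 ratio of 1.73 in the genotype pair (8 of 12 members) and 0.53 in the antibody pair (5 of 12). In the healthy pair they were lower, by a median of -0.82 (7 of 12 members lower, 1 higher; Mertk -1.23, Gas6 -1.18, F13a1 -1.16, Retnla 1.76). Retnla, a gene of alternatively activated macrophages, was at 1.63, 1451, 163 and 890 CPM.

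The planned arthritis contrast called 4 of 10362 myeloid genes by edgeR (593 at an unadjusted p under 0.05; 27 by DESeq2; 1 without the antibody pair), each higher in 2 of 2 genotypes. Ly6c2 rose by 5.56 on the log2 scale (SE 0.344, adjusted p = 0.00865) and the protease inhibitor gene Slpi by 4.44 (SE 0.405, adjusted p = 0.0297). Plac8 rose by 4.32 (SE 0.356, adjusted p = 0.0222) and the coagulation factor gene F10 by 3.93 (SE 0.329, adjusted p = 0.0222). For the shared Notch3 effect edgeR called 0 genes (567 at an unadjusted p under 0.05; 31 by DESeq2; 56 without the healthy pair). Mucl1 (7.11, adjusted p = 0.0541), Hal (-8.58, adjusted p = 0.0541), Ly6c2 (-2.45), Plac8 (-2.53) and Ifi202b (at least 124-fold lower), the latter 3 with adjusted p = 0.0666, had the smallest p-values. Ly6c2 and Plac8 were lower in 3 of 3 pairs, while the other 3 genes had at most 3 UMIs in the antibody pair. In camera, resident macrophage genes lay above others in the Notch3 effect (adjusted p = 0.0229; adjusted p = 0.772 with an estimated correlation) and below in arthritis (adjusted p = 0.00204; adjusted p = 0.861 with an estimated correlation), with Retnla 3.76 in the Notch3 effect, where the healthy pair ran the other way for most members, and Mrc1 -1.78 in arthritis.

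In the 2 arthritic pairs the added model called 14 of 11026 myeloid genes by edgeR (4 rose, 10 fell; 1007 at an unadjusted p under 0.05; 49 by DESeq2). Mucl1 (at least 95.2-fold higher), Ear2 (3.21, SE 0.328, adjusted p = 0.0393) and the lectin gene Clec4b1 (from 27.7 to 180 CPM and from 31.7 to 297 CPM, adjusted p = 0.0294) rose. Ifitm1 fell by 5.40 (SE 0.291, adjusted p = 0.00746), Arg1 fell by 5.96 (SE 0.627, adjusted p = 0.0414), Hal fell by 6.15, Bdh2 fell by 5.34, and Ifi202b was at least 82.0-fold lower. The calls of Mucl1, Hal and Ifi202b rest on the genotype pair, since the antibody pair held 1, 3 and 1 UMIs. Of 12 resident macrophage genes 0 passed (adjusted over the list alone, 7 higher), and of 13 inflammatory macrophage genes Plac8, which fell by 2.78, and Arg1 fell (adjusted over the list alone, 6 lower). All 14 calls were lost without the dendritic-led clusters, where 0 genes passed. Ratios of the pairs had r = 0.392 and rho = 0.304 across 4797 genes, with 262 of 321 (81.6%) in the same direction. Against the healthy pair 128 of 356 (36.0%) and 129 of 239 (54.0%) had the same direction in the genotype and antibody pairs. Cluster 2 held 47.3%, 11.0%, 65.2% and 58.1% of the myeloid cells of the 4 arthritic libraries while cluster 3 held 7.78%, 52.7%, 12.5% and 20.5%. Other scaling moves myeloid ratios by 0.304 in the healthy pair, 0.168 in the antibody pair and 0.253 between the wild-type libraries.

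Mural cells, the pericytes and smooth muscle cells in which Notch3 is most abundant, numbered 13, 26, 11, 33, 23 and 9 in the 6 libraries and were not tested. Rgs5, a pericyte gene, was at 8106 CPM (7450 to 8810) in arthritic wild type against 1932 (1620 to 2280) in the knockout, and at 7599 (7040 to 8190) under isotype against 974 (624 to 1450) under anti-Notch3. It was at 1671 (1310 to 2100) and 2030 (1690 to 2420) in the healthy libraries. Mcam was at 291 (177 to 449) and 112 (48.4 to 221), and at 340 (231 to 482) and 81.1 (9.83 to 293) CPM in the arthritic pairs. Hes1 was at 824 (577 to 1140) in healthy wild type and 300 (178 to 473) in healthy knockout cells, but at 378 (247 to 553) and 672 (496 to 891) in the arthritic genotype pair. Notch targets had median log2 ratios of -0.74, -0.12 and -0.13 in the healthy, arthritic genotype and antibody pairs.

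Whether the Notch3 effect differed between arthritic and healthy joints was examined as the difference of effects in the added model. Its healthy arm is 1 pair, assumed to vary like the arthritic pairs and open to a batch difference, so a call does not show that disease state sets the effect. In fibroblasts the estimated effect on Ccl11 was higher in the arthritic pairs by 3.34 on the log2 scale (SE 0.300, adjusted p = 0.0250), and that on Dkk2, a modulator of Wnt signalling, by 2.67 (SE 0.306, adjusted p = 0.0313). The estimate for Col12a1 was lower in the arthritic pairs, by -3.20 (SE 0.268, adjusted p = 0.0250), as was that for Thbs1, the gene of thrombospondin 1, by -3.87 (SE 0.415, adjusted p = 0.0311). By edgeR 70 fibroblast genes were called (42 higher, 28 lower; 155 by DESeq2), 569 endothelial genes (310 and 259; 77 by DESeq2) and 0 myeloid genes (892 at an unadjusted p under 0.05; 24 by DESeq2). The endothelial calls included 2 of 12 arterial genes (Sox17 at 1.45 and Fbln5 at 1.72), 4 of 10 mural genes higher (Acta2, Myh11, Tagln and Myl9) and Mcam lower, 6 of 16 collagen and matrix genes lower, such as Col1a1 and Sparc, and 3 haemoglobin genes higher. Haemoglobin genes were among the fibroblast calls as well (Hbb-bs 11.79, from 208 CPM in healthy wild type). Mmp3 was lower with knockout in both states, by -2.67 and -4.22, and its difference of effects did not pass (-1.27, SE 0.374, adjusted p = 0.203).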

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

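Of the tests in this part, those of depth per cell and of a strain variant were planned before their results were seen, and the other tests were chosen only afterwards.

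A difference between the arthritic pairs and the lone healthy pair in the effect of targeting Notch3 was called by edgeR for 70 fibroblast and 569 endothelial genes (155 and 77 by DESeq2). The test assumes that the healthy pair varies like the arthritic pairs, and a batch difference between the healthy libraries would enter it. B-lineage cells, outside the classes that were compared, made up 2.86% of healthy wild-type and 2.91% of arthritic knockout cells, and erythroid cells 0.654% and 0.302%, above the limit that a count of 0 allows.

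Genes higher in arthritic than in healthy fibroblasts were lower in the arthritic knockout library: of 103 genes at least 4-fold higher under isotype than in healthy wild type, a choice that leaves arthritic wild type out, 83 of 102 measured were lower than in arthritic wild type (median log2 ratio -1.89). In cells thinned to the same depth their median was -1.785 (72 of 89 lower). For 84 genes chosen in arthritic wild type itself, a choice that favours a low ratio, it was -2.321. Thinned cells weigh alike, so the low ratio does not rest on the deepest cells. Thinning leaves each cell's class and expected proportions unchanged, so it could hardly move these ratios and cannot decide on depth per cell otherwise. Targeting of Notch3 goes with the antibody pair, which had no part in choosing the 84 genes and in which their median was -0.738 (47 of 83 lower), but the isotype library, with no targeting, also lay below arthritic wild type (median -0.569, 41 of 84 lower). A swap of the healthy and arthritic knockout libraries is not excluded by these genes, which were above healthy wild type in the healthy knockout library (median 0.528, 39 of 79 higher, above matched lists), whereas Saa3 in fibroblasts (7.24 and 1.13 CPM in arthritic and healthy knockout), Ly6c2 in myeloid cells (150 and 2.68 CPM) and neutrophils (1.09% and 0.02%) run as the labels say, although the latter 2 were also 23.5 CPM and 0.551% in healthy wild type, without arthritis. Weaker arthritis in the knockout mice for another reason, or a library from mice without arthritis, stays open too: the arthritic knockout library had a median of -0.206 to the healthy knockout library.

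The B-lineage and erythroid cells gathered in 2 libraries whose labels share neither disease state nor genotype. Were the knockout libraries exchanged, or the arthritic knockout library from mice without arthritis, both would come from healthy mice, which these cells do not decide. Of the B-lineage cells, 85.54% in healthy wild type and 64.94% in arthritic knockout held a UMI of the precursor genes Vpreb3, Vpreb1 or Igll1. Precursors of B cells live in bone marrow, so marrow carried over from the bone could be their source. Vpreb3 is among the genes that lead the B-lineage cluster, and the test was chosen afterwards, so a high share was given in advance. These shares therefore do not exclude blood left in the tissue. No biological explanation was tested.

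Ifi202b, an interferon-inducible gene, was at 38.9 and 42.4 CPM in the fibroblasts of the wild-type genotype libraries and at 0.054 CPM or below in the other libraries. Isotype fibroblasts, in which Notch3 was not targeted, had 0 UMIs (upper bound 0.226 CPM), so loss of Notch3 signalling does not account for its absence there. The isotype mice could differ in strain from the wild-type genotype mice, however, so an effect of the knockout is not excluded. The gene lies on chromosome 1 and Notch3 on chromosome 17, which argues against a segment carried along with the knockout. A strain variant between the mice of the genotype libraries could account for it. In both genotype pairs and both classes, 4 genes were 8-fold apart in the same direction and 0 in opposite directions. They were Ifi202b itself and 3 more (Eif3j2, Trim12a and Gm26825). A knockout effect common to both pairs would give the same count. Unlike Ifi202b, the 3 other genes were read in isotype fibroblasts (127, 195 and 23 UMIs). A strain difference would also enter the other ratios of the genotype pairs.

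For the planned Notch3 test, exchanging labels within the pairs makes 4 splits, too few for a share under 0.05. The real split gave 0 fibroblast, 0 endothelial and 0 myeloid genes by edgeR (1081, 560 and 567 at an unadjusted p under 0.05; 172, 29 and 31 by DESeq2), and the highest of the others 0, 13 and 0.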

How the results depend on the processing

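Alternatives without the tendon-led or dendritic-led clusters, and those for the separate Notch3 effects, were chosen after seeing the data. List medians were checked against the exact binomial interval of the main median over the list's members. They stayed within it in 225 of 225 alternatives for the main gene lists and in 1168 of 1186 for other lists (18 moved). This interval is wide for short lists and can cover both directions, so staying within it does not show a kept direction or size. Fibroblast and myeloid shares moved in 19 of 54 alternatives and those of other classes in 11 of 156, and 47 of 95 counts of called genes stayed within 1.5 times. Named genes kept their direction and side of the threshold in 348 of 436, with 66 newly past it, 21 no longer past it and 1 reversed: Cytl1 in the arthritis effect, at -0.122 without the tendon-led clusters. A gene without an adjusted p in DESeq2 counted as keeping its side, which can overstate the agreement. DESeq2 gave none for 6407 of 6885 endothelial genes in the Notch3 effect and 3002 of 7743 in the 2 arthritic pairs. The cause of the shifts was not tested, though fibroblast shares at resolution 2 leave out a cluster that stayed unnamed, as given below.

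Genes called for the Notch3 effect numbered 0 in each class. In fibroblasts there were 172 by DESeq2, 3 with library totals, 43 with no filter on low counts, 3 with stricter cells, 6 without the tendon-led clusters and 0 to 294 with a pair left out. In endothelial cells there were 29 by DESeq2, 235 with no filter and 0 to 933 with a pair left out. In myeloid cells there were 31 by DESeq2, 5 with library totals, 112 with no filter, 4 with stricter cells, 3 without the dendritic-led clusters and 0 to 56 with a pair left out. For arthritis, fibroblasts gave 4 by DESeq2 and 3 with no filter against 0, endothelial cells 1 and 65 against 0, and myeloid cells 27 by DESeq2, 2 with library totals, 142 with no filter and 1 without the antibody pair against 4.

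In the 2 arthritic pairs, the 400 fibroblast genes became 1076 with no filter and 930 without the tendon-led clusters, and the 1069 endothelial genes 160 by DESeq2. The 14 myeloid genes became 49 by DESeq2, 30 with median-of-ratios scaling, 102 with library totals, 456 with no filter, 88 with stricter cells, 31 with doublets kept, 0 without the dendritic-led clusters and 56 with only the arthritic libraries. For the difference between arthritic and healthy effects, the 70 fibroblast genes became 155 by DESeq2, 162 with median-of-ratios scaling, 626 with no filter, 164 with stricter cells, 184 with doublets kept and 575 without the tendon-led clusters. The 569 endothelial genes became 77 by DESeq2, and the 0 myeloid genes 24, 1 with median-of-ratios scaling, 25 with library totals, 346 with no filter, 36 with stricter cells and 1 with doublets kept.

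List tests called at the preset correlation fell to 0 with an estimated correlation in each class and effect, with lowest adjusted p of 0.588 and 0.716 in fibroblasts, 0.527 and 0.623 in endothelial cells and 0.72 and 0.861 in myeloid cells (Notch3 and arthritis). With 2 residual degrees of freedom the correlation is poorly estimated, so this loss leaves the list calls unsettled. Fibroblast shares, from healthy wild type to anti-Notch3, were 57.9%, 58.5%, 41.1%, 59.1%, 66.0% and 45.7% at resolution 2. There a cluster of 1127 cells led by Clic5, Tspan15 and Hbegf stayed unnamed, so part of a lower share can be a lost name. Of stromal cells in the main clustering, fibroblasts were 91.6%, 93.7%, 88.4%, 86.3%, 89.8% and 89.0%. With stricter cells they were 59.1% and 76.1% in the healthy libraries and 41.4% in arthritic wild type, and myeloid shares were 28.1% in healthy wild type, 45.5% in arthritic wild type, 21.7% under isotype and 41.0% under anti-Notch3. Alternatives for mural cells were not run. A lower spread raised recovery in the simulations. At the dispersion of the planned fit, 2-fold changes were recovered in 28.9% of cases in fibroblasts, 13.8% in endothelial and 21.9% in myeloid cells. At a dispersion of 0.02 these were 90.6%, 55.3% and 76.6%. Depth was not varied, so what sets the limit was not settled.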

Other observations

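A few genes of other lists changed in fibroblasts of the 2 arthritic pairs, by the model added after seeing the data. The complement gene C4b rose by 1.60 on the log2 scale with Notch3 targeted (SE 0.196, adjusted p = 0.0189), at 249 and 807 CPM in the genotype pair and 184 and 482 in the antibody pair. It was the sole riser of 10 complement genes (adjusted over the list alone, 5 higher and 1 lower). Of 13 Wnt pathway genes, Dkk2 rose by 1.87 (SE 0.186, adjusted p = 0.0126) and Dkk3 fell by 1.28 (SE 0.159, adjusted p = 0.0192). Adjusted over the list alone, 4 were higher and 1 lower. Of 13 hypoxia genes, Adm rose and the glucose transporter gene Slc2a1 fell (adjusted over the list alone, 3 higher and 4 lower). Of 12 genes of the TGF-beta response Inhba fell (adjusted over the list alone, 1 higher and 5 lower).

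Antigen presentation genes of myeloid cells were higher under anti-Notch3 than under isotype by a median log2 ratio of 1.05 (7 of 10 members higher, 0 lower), with Cd74 at 20240 against 8410 CPM. In the arthritic genotype pair the median was 0.22 (0 of 10 higher, 2 lower). Cluster 9, led by Cd209a, Retnla and Mgl2 and rich in Cd74, held 4.01% of isotype and 14.1% of anti-Notch3 myeloid cells, and 1.57% and 25.1% in the genotype pair. Interferon response genes of myeloid cells had a median of 2.29 in arthritic over healthy wild type (17 of 18 higher) and -1.72 in arthritic knockout over arthritic wild type (13 of 18 lower), Isg15 being at 9.41, 451 and 37.6 CPM in healthy wild type, arthritic wild type and arthritic knockout. No replicate checks these ratios.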
